A study of Mus musculus with 12 samples.

How the data were processed

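RNA from CD8+ T cells of mouse lymph nodes had been sequenced at 6 circadian times on each of 2 days, which gave 12 libraries. The labels name TRIzol and RNeasy for the RNA and a KAPA HyperPrep kit with polyA selection for the libraries. Per the submitters' processing notes, the tools were bcl2fastq 2.19, Trimmomatic 0.35, STAR 2.5.1b and RSEM 1.2.28 on the mouse build GRCm38. The gene annotation behind the files was not given in the sources used here.

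The authors deposited 1 table of read counts per gene for each library, in the layout that STAR writes, with 1 column for each way of treating strand. These counts were not normalised. Column 4 was used, since 77.6% to 80.9% of the fragments in the other stranded column matched no gene, against 11.4% to 13.9% in column 4. The 4 rows of each table that name no gene (unmapped, multimapping, no feature, ambiguous) held 29.3% to 31.2% of the fragments and were left out of library sizes and tests. The authors also deposited RSEM tables, with expected counts (estimated counts that need not be whole), TPM and FPKM per gene. The deposited TPM values were scaled by RSEM to the same sum in each library, and the deposited FPKM values were scaled to gene length and library size. The files held 50600 gene identifiers. Of these, 50376 matched a symbol in GENCODE release M21 of GRCm38, 45737 of them with the same version number. Coordinates are those of that annotation.

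Counts were analysed with edgeR 4.0.16 in R 4.3.3. The edgeR filter filterByExpr, with the circadian time as the group, kept 16396 genes, and TMM factors set the scaling. Values in CPM are counts scaled to library size with the TMM factors. All tests were edgeR's quasi-likelihood F tests with Benjamini-Hochberg adjustment, and a gene passed at an adjusted p under 0.05. The 24 h test asked whether a cosine and a sine of 24 h period together differed from 0. Its amplitude is the log2 distance from the mean to the peak, and ± after an amplitude, a peak time or a log2 difference is a standard error. The 12 h test added a cosine and a sine of 12 h period. The test of circadian times compared the 6 times with 5 coefficients and so allowed any shape. The day test compared 6 libraries of day 1 with 6 of day 2 beside the 24 h wave, and the interaction test asked whether the 24 h wave differed between days. After the values were seen, CT14 and CT10 were each also contrasted with the mean of the other times. The common biological coefficient of variation was 0.0967.

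The labels make the replicate number the day of collection, so it pairs the libraries of 1 day. The 24 h, 12 h and circadian time tests and the list scores had no day term, and the day entered them only as a block in an alternative. Over 10153 genes, the deviations of day 2 from day 1 correlated between the 15 pairs of circadian times from -0.60 to 0.35 (median 0.08), with 6 of the 15 above 0.1.

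Tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. Of 29 lists, 28 had at least 3 tested genes and were scored as the mean over members of standardised log2 CPM (prior count 2). A score's F value was tested with 100000 permutations of the 12 libraries, a one-sided test on F that counts waves of any direction, and adjusted over the lists. The same score test over the 6 circadian times was added after the data were seen. For each list, 2 counts of members are given, 1 over all tested genes and 1 "adjusted over the list alone". Correlations across libraries used 100000 two-sided permutations. They treated the 2 libraries of a time as independent, so a difference among times that both genes share can make the p-value too small. Agreement of peak times between days was measured by choosing the 200 genes of smallest p on 1 day and comparing their peak on the other day, with 100 permutations of the times.

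The naming rule took, for the 24 h test, every tested core clock and clock output gene, the 12 largest amplitudes among passing genes with a mean of at least 5 CPM, the 2 genes of smallest p in every other list, and Cirbp, Rbm3, Cd8a, Cd8b1 and Cd3e. It took the 4 genes of smallest p for the 12 h test and for the interaction, also with a mean of at least 5 CPM, and the 5 largest changes each way among passing genes for the day test. Predicted genes and unnamed cDNA clones were left out, and a few genes that the rule took are not given in the text. It named no gene for the test of circadian times, so genes named there that no other part of the rule covers were chosen after their values were seen.

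The tests were checked on simulated counts drawn from the means, spread and library sizes of these libraries, with changes given to genes of at least 5 CPM. Of 50 genes given a 24 h amplitude of 0.2 log2, 28% were recovered, and of those given 0.4, 86%. The simulated genes varied independently of each other, without differences shared between libraries, so recovery in the real data may be lower. Of 50 genes given a change of 0.6 log2 at CT14 alone, the test of circadian times recovered 76% and the 24 h test 0%. The alternatives were DESeq2 1.42.0 as the test and as the scaling, no filter on low counts, rounded expected counts, limma 3.58.1 on log2(TPM + 1) and log2(TPM + 0.1), a Kendall rank test, a linear trend, a score of B cell markers as covariate, the day as a block, and leaving out each library. Counts without strand, a score of monocyte and macrophage markers as covariate, libraries thinned to the smallest total, and fits without CT14, without CT2 or without CT2 and CT6 of day 1 were added after the data were seen. When 1 library was left out, its time kept 1 library, which was assumed to vary like the others. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Counts on genes summed to between 24689964 and 33497078 per library, which set the depth.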

Results

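Polyadenylated RNA was measured in CD8+ T cells, the cytotoxic lymphocytes, from lymph nodes of male mice aged 8 weeks. The C57BL/6J animals were kept in constant darkness, where daily rhythms run on the internal clock. Collection took place at circadian times (CT) 2, 6, 10, 14, 18 and 22 h on each of 2 days. By convention the subjective day runs from CT0 to CT12 and the subjective night, when mice are active, from CT12 to CT24. Each time had 2 libraries, 1 per day. The labels do not say how many mice went into a sample, so p-values measure only the spread between these samples. Counts on genes ranged from 24689964 to 33497078 per library, and the CT14 libraries were the deepest with 32205484 and 33497078. The co-receptor genes Cd8a and Cd8b1 stood at 1406 ± 99.6 and 1119 ± 94.1 CPM (SD, n = 12), and Cd3e, a part of the T cell receptor complex, at 552 ± 38 CPM (SD, n = 12). The 2 libraries of a time differed by more than counting noise at each of the 6 times, with a chi-square per degree of freedom from 3.07 at CT18 to 40.2 at CT2.

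The series title asks which transcripts of these cells follow a 24 h cycle. The genes of the molecular clock had waves of small amplitude, and none passed the test over all genes. Arntl, whose product BMAL1 drives the clock with CLOCK, had an amplitude of 0.08 ± 0.04 log2, and Clock itself 0.02 ± 0.03. The repressor gene Per2 ranged from 10.3 to 16.2 CPM, with an amplitude of 0.23 ± 0.05 and a fitted peak at 19.0 ± 0.77 h. Nr1d1, which encodes the repressor REV-ERBα, ranged from 4.86 to 8.63 CPM with an amplitude of 0.26 ± 0.06 and a peak at 10.6 ± 0.85 h, and its relative Nr1d2 had an amplitude of 0.09 ± 0.04. Dbp and Tef, which encode clock-controlled PAR bZIP factors, had amplitudes of 0.17 ± 0.04 and 0.18 ± 0.04 with peaks at 11.7 ± 0.84 and 11.9 ± 0.80 h.

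The 22 tested clock genes, 12 core and 10 output, had amplitudes from 0.02 to 0.28 log2 with a median of 0.15. Among the 17 with at least 5 CPM the largest was 0.27 ± 0.09, for the period gene Per3, a 1.45-fold step from trough to peak, and no amplitude plus 2 standard errors exceeded 0.45. Of the 22, 6 had an unadjusted p under 0.05 and none passed over all genes, while 2 core and 2 output genes passed when adjusted over the list alone. Of the other core genes, Npas2, Per1, Cry1, Cry2 and Rora had amplitudes of 0.28, 0.05, 0.10, 0.12 and 0.10, and Npas2 had a mean of 0.30 CPM. The output genes Hlf, Nfil3, Bhlhe40, Bhlhe41, Ciart, Wee1, Nampt and Usp2 had 0.28, 0.18, 0.19, 0.16, 0.23, 0.14, 0.11 and 0.11. Per2 lies on chromosome 1 at 91415982 to 91459324 (ENSMUSG00000055866.9), and Nr1d1 on chromosome 11 at 98767932 to 98775333 (ENSMUSG00000020889.11).

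**Figure D1:**
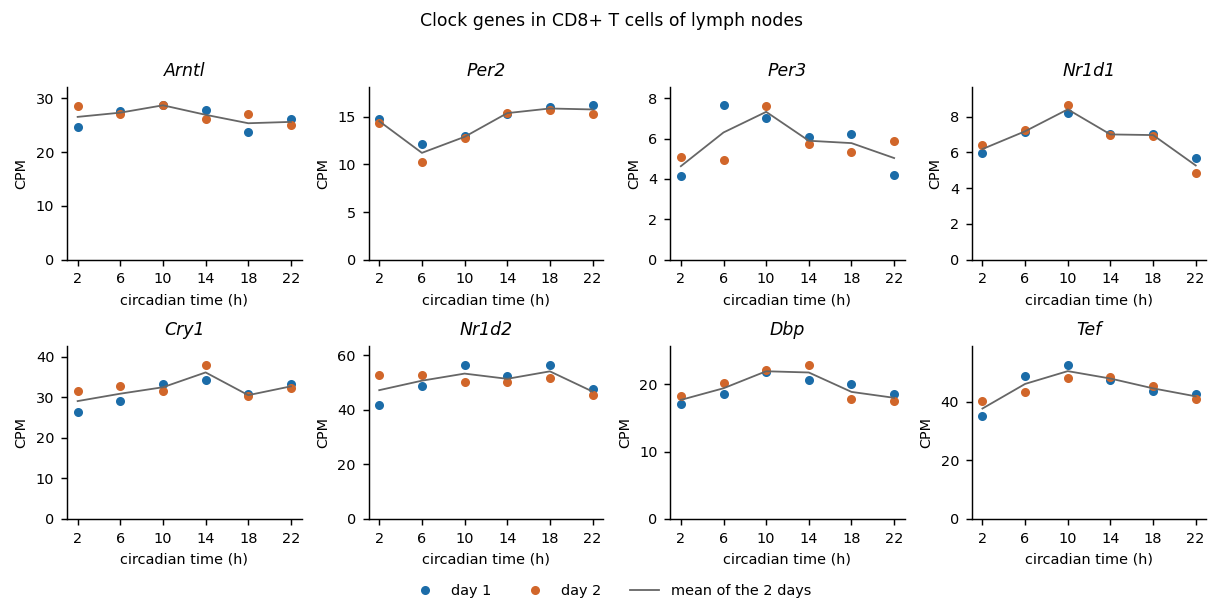
Normalised counts (CPM) of 8 clock genes against circadian time in hours; points are the libraries of day 1 and day 2, and the line joins their means at each time. Axes start at 0, and Per2 moves between 10.3 and 16.2 CPM while Arntl stays between 23.7 and 28.7 CPM.

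Over the whole transcriptome, 0 of 16396 genes passed the 24 h test, with a smallest adjusted p of 0.238 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. At an unadjusted p under 0.05 there were 2183 genes, where 819.8 are expected by chance. DESeq2 called 246 genes, among them Per2, Nr1d1, Dbp and Tef, while limma on TPM and the Kendall rank test each called 0. The count stayed at 0 without CT14 and rose to 145 without CT2 of day 2 and to 431 without both CT2 libraries. The 2183 genes peaked in all parts of the cycle, 1002 of them in the subjective day and 1181 in the night, most often from 4 to 8 h (484 genes) and from 20 to 24 h (467 genes).

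Outside the clock, stress and temperature genes were among those with small unadjusted p for a 24 h wave. Rbm3 and Cirbp encode RNA-binding proteins that are induced by mild cold. Rbm3 had an amplitude of 0.31 ± 0.05 with a peak at 6.99 ± 0.61 h (unadjusted p = 8.9e-05, edgeR), and Cirbp 0.43 ± 0.10 with a peak at 6.04 ± 0.92 h. The inducible Hsp70 genes Hspa1a and Hspa1b, near-identical copies whose counts are uncertain where reads are shared, had a fitted peak at 16.8 h, with amplitudes of 2.13 ± 0.39 and 2.104 ± 0.36. Hk2, which encodes a hexokinase of glycolysis, had 0.32 ± 0.07 at 19.9 h, and Cish, a feedback inhibitor of cytokine signalling, 0.34 ± 0.07 at 13.4 h. The folding factor genes Calr and Hyou1 of the endoplasmic reticulum had 0.18 ± 0.04 at 20.96 h and 0.14 ± 0.03 at 19.1 h. The mitochondrial genes mt-Nd1 and mt-Nd2 had 0.18 ± 0.04 each, near 0.87 and 23.5 h. None of these passed after adjustment, and Cd8a, Cd8b1 and Cd3e had amplitudes of 0.01, 0.04 and 0.05.

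Of the other genes named by rule, Zeb2, which effector T cells and myeloid cells express, had the largest amplitude outside the marker lists, 0.49 log2. It moved with the myeloid markers, lowest in CT10 of day 1 (11.9 CPM) and CT2 of day 2 (15.8 CPM) and highest in CT22 of day 2 (50.7 CPM). In T cell receptor signalling these were Txk (0.12) and Ptpn6 (0.12), in PI3K signalling Pik3ip1 (0.24) and Sesn1 (0.14), in effector function Tnf (0.14), and among naive T cell genes Dapl1 (0.22) and Klf3 (0.15), as log2 amplitudes. Clock modifiers Timeless and Btrc had 0.16 and 0.12, the immediate early genes Egr2 and Dusp1 0.17 and 0.33, and the interferon gene Igtp 0.13. For Socs1, Gins2, Ccne1, Rpl3 and Rpl22 the amplitudes were 0.19, 0.19, 0.10, 0.11 and 0.15. Heatr1, Nop2, Ndufs1 and Cox5a had 0.10, 0.11, 0.09 and 0.10. Scd2, Srebf2 and Pgam1 had 0.15, 0.10 and 0.11. None of these genes passed the 24 h test after adjustment.

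Across the 6 circadian times without an assumed shape, the clearest event was a rise of chaperone genes at CT14, early in the subjective night. Hsph1, which encodes the co-chaperone Hsp110, rose to 349.5 ± 23.5 CPM at CT14 (SD, n = 2) against 93.0 ± 4.23 CPM at CT6, a 3.76-fold step. Stip1, the adaptor between Hsp70 and Hsp90, stood at 285 ± 11.8 CPM at CT14 against 130.02 ± 10.6 at CT6. Hspa8, the constitutive Hsp70, stood at 2166 ± 117 CPM against 1143 ± 41.96 at CT6 (SD, n = 2). Dnajb1, Dnaja1 and Chordc1, which encode further co-chaperones, were 0.70 ± 0.06, 0.83 ± 0.08 and 0.77 ± 0.06 log2 higher at CT14 than at the other times. Both CT14 libraries exceeded all 10 others for Hsph1 and Hspa8.

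Of the 18 heat shock genes, 12 differed among the times over all genes (Hsph1, Stip1, Chordc1, Dnajb1, Fkbp4, Hspa1a, Hspa1b, Dnaja1, Ahsa1, Hspa4l, Hspd1 and Hspa8) and 14 adjusted over the list alone. In all 18 the CT14 mean was above the mean of the others, by a median of 0.65 log2, and 13 of them rose in that contrast. Without either CT14 library 2 of the 12 passed, without CT6 of day 1 5 did, and without any 1 of the CT10, CT18 or CT22 libraries 8 did. Hspa1b rose from 0.70 ± 0.19 to 19.9 ± 4.19 CPM between CT6 and CT14 (SD, n = 2). Hsp90ab1 was 0.42 ± 0.06 higher and passed the contrast alone, while Hsp90aa1, at 0.63 ± 0.14, passed neither test. The enrichment of the list among passing genes had an adjusted p of 7.5e-27 by Fisher's exact test. That test counts genes as independent, though all were measured in the same 12 libraries, so its p-value may be far too small. The list score had a permutation p over times of 0.0089 (adjusted 0.0911), so the score as a whole did not pass. Hsph1 lies on chromosome 5 at 149614287 to 149636376 (ENSMUSG00000029657.15), and Hspa8 on chromosome 9 at 40800984 to 40810087 (ENSMUSG00000015656.17).

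**Figure D2:**
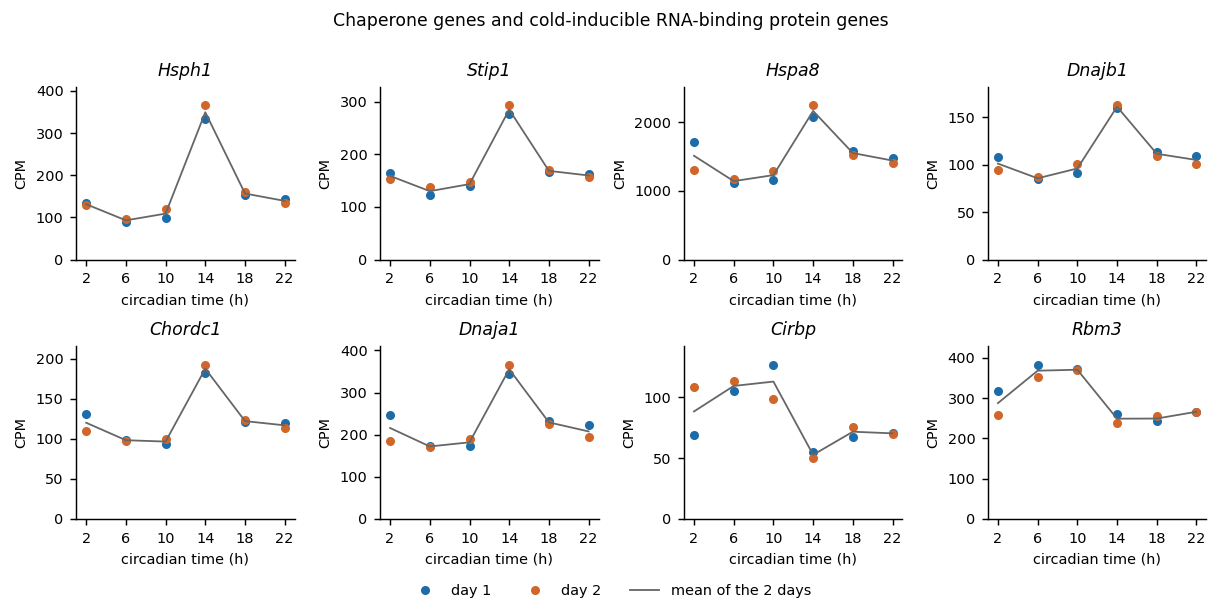
Normalised counts (CPM) of 6 chaperone genes and of Cirbp and Rbm3 against circadian time in hours; points are the libraries of day 1 and day 2, and lines join their means. Hsph1 reaches 333 and 366 CPM at CT14, and Cirbp is at its lowest there with 54.9 and 50.4 CPM.

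Of the cold-inducible genes, Cirbp was lowest where the chaperones were highest. Rbm3 changed among the times, from 370.4 ± 2.43 CPM at CT10 to 249 ± 16.6 at CT14 (SD, n = 2), but was as low at CT18 (249 ± 8.00) and 266 ± 0.76 at CT22, and it did not pass the contrast of CT14 with the other times. Cirbp was 0.75 ± 0.14 log2 lower at CT14 than elsewhere, at 52.7 ± 3.20 CPM. Its adjusted p in that contrast, chosen after the values were seen, was 0.0377 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Cirbp did not pass the planned test of circadian times. Across the 12 libraries the heat shock score correlated with Cirbp at Pearson r = -0.93 (permutation p = 1e-05, the smallest possible, adjusted 4e-05 over 4 relations) and Spearman rho = -0.92 (permutation p = 6e-05). Without the CT14 libraries, the farthest from the median score, r was -0.95, and within day 1 and day 2 it was -0.94 and -0.94. With Rbm3 the score had r = -0.72 (permutation p = 0.0077, adjusted 0.0103) and rho = -0.74 (permutation p = 0.00817), r = -0.76 without the CT14 libraries, and -0.78 and -0.67 within the days. The permutations for both genes treated the 2 libraries of a time as independent, so these p-values may be too small.

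At CT10, late in the subjective day, some genes known to respond to glucocorticoids stood high. Of the 19 in the list, 10 were above the mean of the other times there, with a median of 0.09 log2, and Dusp1, Cebpb and Cebpd, which respond to the hormone too, had their lowest mean at CT10. Ddit4, an inhibitor of mTOR signalling, rose to 112 ± 1.48 CPM at CT10 (SD, n = 2) against 56.0 ± 5.83 at CT6, the only gene to pass the contrast of CT10 with the other times (adjusted p = 0.0178, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Cxcr4, the receptor for the bone marrow homing chemokine CXCL12, changed among the times, from 56.8 ± 1.94 CPM at CT2 to 99.4 ± 3.91 at CT10 (SD, n = 2). Tsc22d3, the glucocorticoid-induced leucine zipper gene, had 264 and 228 CPM at CT10 and from 117 to 173 CPM in the other 10 libraries, and missed the adjusted threshold with 0.0694 in edgeR's test of times with Benjamini-Hochberg adjustment. Il7r, the receptor gene for the survival cytokine interleukin 7, had 620.2 and 602 CPM at CT10 and 425 and 427 at CT14, and missed it as well. Summed monocyte and macrophage markers were lowest at this time, at 648 ± 228 CPM against 1571 ± 277 at CT22 (SD, n = 2). Of the list, 2 genes differed among times over all genes and 5 adjusted over the list alone, and the score had a permutation p of 0.0116 (adjusted 0.0911).

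Tsc22d3 correlated with Cxcr4 at r = 0.71 (permutation p = 0.00632, adjusted 0.0103) and rho = 0.69 (permutation p = 0.0175), with 0.46 without the CT10 libraries (permutation p = 0.182, n = 10) and 0.88 and 0.64 within day 1 and day 2. With Il7r it had r = 0.67 (permutation p = 0.0163, adjusted 0.0163) and rho = 0.52 (permutation p = 0.0834). Without the CT10 libraries r was 0.12, so the relation with Il7r rests on them, and within the days it was 0.74 and 0.52. These belong to the same 4 relations, with the same limit on their permutation p-values.

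**Figure D3:**
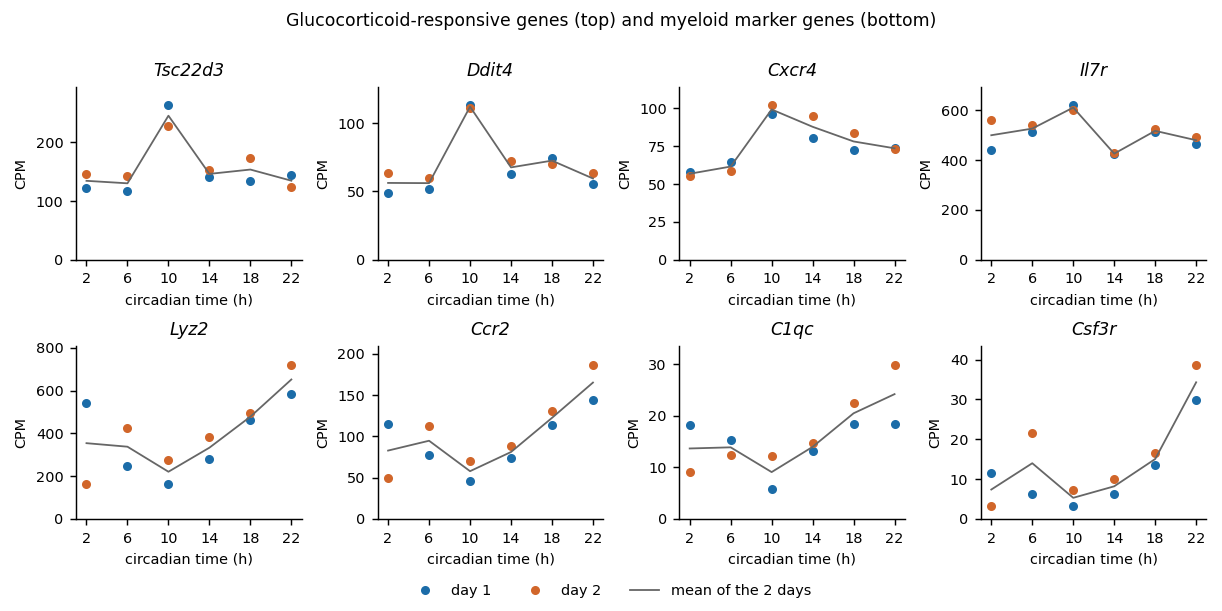
Normalised counts (CPM) of Tsc22d3, Ddit4, Cxcr4 and Il7r and of the myeloid markers Lyz2, Ccr2, C1qc and Csf3r against circadian time in hours; points are the libraries of day 1 and day 2, and lines join their means. Tsc22d3 reaches 264 and 228 CPM at CT10, and Lyz2 spans 165 to 722 CPM.

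In all, 42 genes differed among the circadian times and 2086 had an unadjusted p under 0.05. Their highest mean fell at CT14 in 29, at CT10 in 8, at CT2 in 4 and at CT6 in 1, and their lowest at CT6 in 25. Beside chaperones, CT14 was highest for Lbp, which encodes a lipopolysaccharide-binding protein (8.67 ± 0.77 CPM against 2.65 ± 0.15 at CT10), and lowest for the urea transporter gene Slc14a1 (42.6 ± 2.996 CPM). Cpt1a, the gate of mitochondrial fatty acid oxidation, was highest at CT6 with 103 ± 11.3 CPM and lowest at CT2 with 53.9 ± 0.89 (SD, n = 2). In the contrast of CT14 with the other times, chosen after the values were seen, 93 genes were higher and 93 lower. With the day as a block 20 of the 42 passed, 8 of the heat shock genes among them, and without CT14 none did. Leaving out CT2 of day 1 or of day 2 gave 664 or 1745 genes, and without both 527. Leaving out CT6 of day 1 or of day 2 gave 14 or 45, CT10 21 or 23, CT14 7 or 6, CT18 19 or 19, and CT22 21 or 19.

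In the 12 h test 8 genes passed, all of them among the 42 that differed among times, and 6 were highest at CT14. The 4 named by rule were Gprasp1, Ccr9, Ksr2 and Parp3. Ccr9, the receptor gene for gut homing, was high at both CT2 and CT14 (212 ± 15.0 and 209 ± 6.61 CPM) and low at CT6 and CT10 (152 ± 0.44 and 153 ± 6.74; SD, n = 2), a 12 h amplitude of 0.26 log2. Gprasp1, Ksr2 and Parp3 had 12 h amplitudes of 0.25, 0.51 and 0.21. The other 4, chosen after their values were seen, were Lbp, Ahsa2, Fkbp4 and St13. With the day as a block 4 genes passed, and without CT14 0 did. Leaving out either CT14 library or CT10 of day 2 gave 0 genes, CT18 of day 1 or day 2 gave 3 or 1, CT2 of day 1 gave 3, CT22 of day 2 gave 4, CT6 of day 1 gave 2, and CT2 of day 2 gave 93. At an unadjusted p under 0.05 there were 999 genes.

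Between the 2 days the B cell genes had the smallest p. Fcer2a and Cr2, which encode surface proteins of B cells and were chosen after their values were seen, had a log2 difference of day 2 from day 1 of -0.49 ± 0.09 and -0.52 ± 0.10. After adjustment 0 genes passed in edgeR's quasi-likelihood test, with 299 at an unadjusted p under 0.05, and DESeq2 called 6. Summed B cell markers averaged 3126 ± 315 CPM on day 1 and 2900 ± 352 CPM on day 2 (SD, n = 6). Without CT2 of day 2, 2 genes passed.

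The 24 h wave did not differ detectably between the days for any gene, with 0 genes in edgeR's quasi-likelihood test, 0 in DESeq2 and 728 at an unadjusted p under 0.05. Gabbr1, Mier2, Cxcl9 and Fam193b, named by rule, had the same adjusted p of 0.825 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Leaving out CT2, CT18 or CT22 of day 2 gave 1 gene each. Of the 200 genes most rhythmic on day 1, 90.0% peaked within 4 h of that time on day 2, where permuted times gave a mean of 36.8% and reached as much in 8 of 100. Selected on day 2, 50% did so on day 1, against 30.0%, reached in 17 of 100.

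Markers of some other cell types, above all of monocytes, macrophages and neutrophils, varied widely between libraries. The myeloid genes Lyz2 (lysozyme), Ccr2 and C1qc ranged over 165 to 722, 45.9 to 187 and 5.87 to 29.9 CPM, and were lowest in CT10 of day 1 and, for Lyz2 and Ccr2, nearly as low in CT2 of day 2. Summed monocyte and macrophage markers went from 487 CPM in CT10 of day 1 to 1767 CPM in CT22 of day 2, 3.63-fold. The sums spanned 7.88-fold for neutrophils, 2.59-fold for NK cells, 1.95-fold for dendritic cells, 1.72-fold for stroma and endothelium, 1.51-fold for B cells and 1.43-fold for CD4 T cells. The single tested erythroid gene, Hbb-bs, had a mean of 0.93 CPM. Of 15 monocyte and macrophage markers, 13 had an unadjusted p under 0.05 for a 24 h wave, 0 passed over all genes and 10 adjusted over the list alone. The markers moved together, so these counts are not independent. Their score as a whole did not pass for a 24 h wave (permutation p = 0.103, adjusted 0.459). Ccr2 and C1qc each had an amplitude of 0.58 ± 0.15 log2, with peaks at 21.5 and 20.9 h. Csf3r and S100a9, of neutrophils, had 0.97 ± 0.30 and 0.80 ± 0.26, and Fcer1g and Tyrobp, shared by NK and myeloid cells, 0.45 ± 0.15 and 0.31 ± 0.14. The other marker genes named by rule, Cr2, Blk, Izumo1r, Zbtb7b, Ccl22, Fscn1, Cxcl13 and Pecam1, had 0.30, 0.16, 0.12, 0.23, 0.21, 0.17, 0.59 and 0.14.

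No list of 28 passed as a whole for the 24 h wave (edgeR was not used here, since each score is 1 value per library). Cytosolic ribosomal protein genes summed to 83104 CPM in CT2 of day 1, against means of 58697 to 64253 CPM at the other 5 times. Mitochondrially encoded transcripts had the smallest permutation p, 0.00624 (adjusted 0.175), and the others had adjusted values from 0.341 to 0.970. Over circadian times, heat shock, glucocorticoid response, folding in the endoplasmic reticulum and mitochondrially encoded transcripts each had an adjusted permutation p of 0.0911, and the other 24 lists, with the clock, cell cycle, ribosome, glycolysis, oxidative phosphorylation, sterol, interferon and T cell lists among them, 0.520 to 0.964. Folding genes had 12 of 19 members past 0.05 adjusted over the list alone and 0 over all genes.

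**Figure D4:**
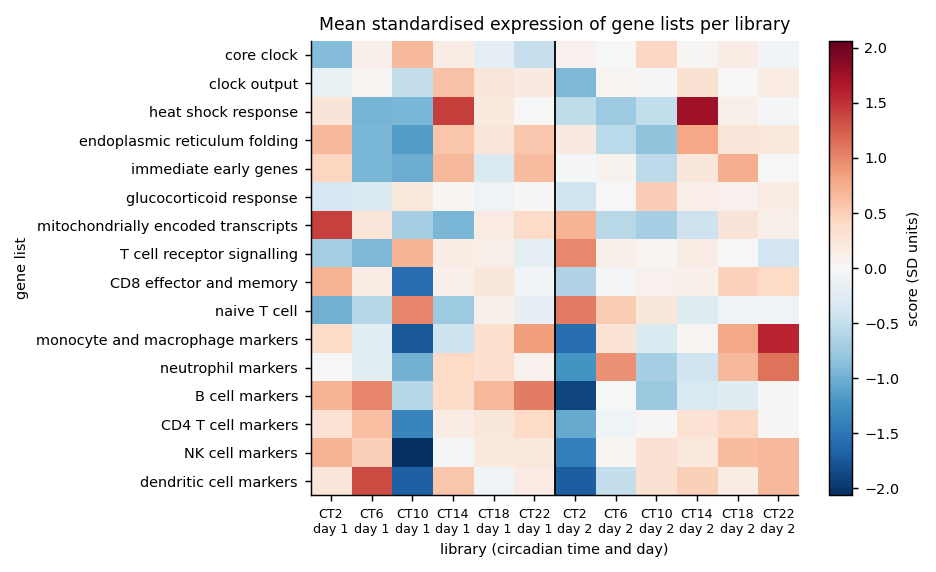
Mean standardised expression (SD units, colour) of 16 gene lists in the 12 libraries, ordered by day and circadian time. The heat shock score is highest in the CT14 libraries of both days (1.43 and 1.75), and most marker scores are lowest in CT10 of day 1 and CT2 of day 2.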

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

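The tests of depth, of immediate early genes, of Cirbp and Rbm3, of marker pairs, of the B cell markers and of a swap, the permuted marker scores, and the counts of splits at an unadjusted p for the times and the days, were chosen only after the result was seen, as were the fits on thinned libraries and with the monocyte score.

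In groups of 6 libraries of the same day, 8 values stood far from the nearest of the others, in 38 sets tested; chance picks out about 1 in 20 groups. CT14 of day 2 had 33.497 M (mega) counts on genes, where the next library of that day had 27.073. CT2 of day 1 had an FPKM sum of 867.48 k (kilo), next to 783.04. Summed heat shock genes stood at 7763.3 CPM in CT14 of day 2, next to 5322.8, and summed glucocorticoid response genes at 2726.4 CPM in CT10 of day 1, next to 2215.8. B cell markers were low in CT10 of day 1 (2495.6 CPM, next to 3167.7) and in CT2 of day 2 (2206.1, next to 2950.3), and CD4 T cell markers in CT10 of day 1 (157.27, next to 204.79). Markers of stroma and endothelium were high in CT6 of day 1 (246.8 CPM, next to 180.87).

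The rise of chaperone genes at CT14 came with the deepest libraries and the lowest Cirbp, and 2 of the 12 called genes passed without either CT14 library and 5 without CT6 of day 1. After thinning every library to the smallest total, 12 of the 12 heat shock genes still passed, and with the monocyte and macrophage score as covariate 12 did too, which argues against depth and against these cells as the cause. Immediate early genes, which respond to handling, were 0.073 log2 higher at CT14 (median; quartiles 0.0061 and 0.16) against 0.65 for heat shock genes, which argues against a stress that moves both. Cirbp and Rbm3 ran opposite to the heat shock score, with the weaker correlation at -0.72 and at -0.76 without the CT14 libraries (permutation p = 0.0168, n = 10), though Rbm3 was as low at CT18, so a candidate explanation is a shared temperature-like input, from body temperature or from the handling of the tissue. The circadian time stays open as a hypothesis beside a warmer preparation of both CT14 samples, since no temperature was given.

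The CT2 libraries of day 1 and day 2 differed more than those of any other time, with an SD over genes of 0.3498 log2 against 0.243 for the next pair, and myeloid markers differed up to 3.63-fold between libraries. With the trend in gene length removed the SD of CT2 was still 0.333 against 0.240, which argues against length bias alone. A swap of CT2 and CT10 of day 2 cannot be told apart from the labels as given. Exchanged, the pairs had deviations correlated at 0.76 and -0.28, and as labelled at 0.29 (CT10) and -0.21 (CT2). CT6, which no exchange touches, had -0.17. Of 17 clock genes, 8 differed the same way between CT2 and CT10 on both days, Nr1d1, Dbp and Tef among them. The others differed opposite ways, and over the 17 the differences of the days had r = -0.075. With the monocyte and macrophage score regressed out the SD fell to 0.217, below the 0.246 of the next pair, where 20 of 1000 permuted scores went as low. The NK and dendritic cell scores were low in CT2 of day 2 too (-1.41 and -1.70), as was the B cell score. None of these was regressed out, so the fall cannot be tied to monocytes and macrophages in particular. The monocyte and macrophage markers moved together (median r = 0.92 over 105 pairs, lowest 0.76), so more or fewer of these cells in a library may be the source. From CT10 of day 1 to CT22 of day 2, their lowest and highest libraries, these markers rose by a median of 2.13 log2 and B cell markers by 0.28. For that pair, picked by the myeloid markers, this argues against a lower share of CD8 T cells alone. Between the CT2 libraries, however, the B cell score fell from 0.70 on day 1 to -1.89 on day 2. The monocyte and macrophage score fell from 0.40 to -1.58, so for CT2 a changed share of CD8 T cells stays open. Whether the content of myeloid and other cells in the lymph node follows the circadian time, or the isolation of the cells in each sample set it, stays open.

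Redrawing which libraries belong to which time shows how far chance can be excluded. For the 42 genes that differed among times, 12 of 100 splits gave as many, the real one included, with up to 362 genes, so chance cannot be excluded for this count. At an unadjusted p under 0.05 the same test gave 2086 genes, which 4 of 100 splits reached, the real one included, with up to 2537. That lies narrowly below the bound of 5 of 100. The measure was added after the result was seen and the planned count did not meet the bound, so chance was not excluded. With up to 362 genes, splits point to a structure of the samples. Of the 11 others with as many genes, 10 put CT2 of day 2 with CT10 of day 1, both low in markers of other cells, and 3 kept the CT14 libraries together. Among all 99 redrawn splits, 12 made the first of these pairs and 13 the second, and 0 with neither pair gave as many genes. With the day as a block 20 genes passed. For the 2183 genes with an unadjusted p under 0.05 in the 24 h test, 5 of 100 splits gave as many, with up to 3219, and chance could not be excluded. For day 1 against day 2, with 0 genes by edgeR, 299 at an unadjusted p under 0.05 and 6 by DESeq2, a count of 0 is reached by all 100 of 100 splits by construction (up to 41 genes), so it says nothing. The 299 genes were reached in 84 of 100 splits, with up to 3149, and chance could not be excluded.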

How the results depend on the processing

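Counts without strand, the monocyte score, thinning, the fits without CT14, without CT2 or without CT2 and CT6 of day 1, and the list scores over times were chosen only after the result was seen. The 24 h count of 0 genes (edgeR; 2183 at an unadjusted p under 0.05) became 246 with DESeq2, 323 with no filter and 431 without CT2, and ranged from 0 to 145 with 1 library left out (145 without CT2 of day 2); under the other alternatives it was 0, limma and the Kendall rank test included. DESeq2 and no filter shared 129 of their genes. In 20 splits, DESeq2 gave 246 or more in 2 and no filter 323 or more in 7, with up to 784 and 1818. No filter raised the number of genes tested to 29911 and the prior degrees of freedom from 4.84 to infinite, which pools the spread of all genes. Peaks from CT0 to CT12 numbered 0 for passing genes, 1002 at an unadjusted p under 0.05, 109 with DESeq2, 86 with no filter, 95 without CT2 and 0 to 16 with 1 library left out (16 without CT2 of day 2). The 42 genes that differed among times became 516 with DESeq2, 209 with the monocyte score, 2146 with no filter, 527 without CT2, 20 with the replicate block and 0 without CT14. In 20 splits, DESeq2 reached 516 in 3, with up to 787, and no filter 2146 in 1, the real one, with a median of 1048 and up to 2132. All 42 were among those of the first 4, and the 20 were all among the 42. With 1 library left out the count ranged from 6 without CT14 of day 2 to 1745 without CT2 of day 2, with 664 without CT2 of day 1, 14 without CT6 of day 1, 7 without CT14 of day 1, 21 and 23 without CT10 of day 1 and day 2, 19 without either CT18 library, and 21 and 19 without CT22 of day 1 and day 2. The 8 genes of the 12 h test became 68 with DESeq2, 548 with no filter, 25 without CT2, 4 with the replicate block and 0 without CT14, and ranged from 0 to 93 with 1 library left out: 93 without CT2 of day 2, 4 without CT22 of day 2, 3 without CT18 of day 1 or CT2 of day 1, 2 without CT6 of day 1, 1 without CT18 of day 2, and 0 without CT10 of day 2 or either CT14 library. The day count was 6 with DESeq2 and 0 to 2 with 1 library left out (2 without CT2 of day 2), and the interaction 0 to 1 (1 without CT2, CT18 or CT22 of day 2). For lists the 24 h count was 0 to 1 with 1 library left out (the monocyte and macrophage list, without CT2 of day 2), and over times 0 to 2 (heat shock and clock output, without CT2 of day 1). Of 2106 values of single 24 h waves, 2042 kept the outcome of not passing at an adjusted 0.05, which does not measure whether amplitude or peak stayed the same. Another 63 passed where the reported value did not. A reversal, a peak moved by more than 6 h, was counted only for genes with a reported unadjusted p under 0.05. By that count Fcer1g alone reversed, with a peak at 9.53 h with the monocyte score as covariate against 21.1 h. The cause of these differences was not tested, beyond the fewer samples or more genes that an alternative has by construction. At the depth here, simulated 24 h amplitudes of 0.2 log2 were found in 28% of genes and those of 0.4 in 86%. Simulated genes varied independently, without the differences between libraries that many genes share here, so these shares may be too high. In the real 24 h test by edgeR, Hspa1b had an amplitude of 2.104 log2, an unadjusted p of 0.00018 and an adjusted p of 0.238. That adjusted p was the smallest of the test, shared with other genes such as Per2 and Rbm3. Hspa1b peaked sharply at CT14, from 0.46 CPM in CT10 of day 1 to 22.9 in CT14 of day 2. It was thus unlike the simulated cosine waves and does not measure their recovery.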

Other observations

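The contrast of CT6 and CT10 with the other times and the correlations of Il7r and Cxcr4 with Tsc22d3, with their criterion, were chosen only after the result was seen.

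Some folding genes of the endoplasmic reticulum were low at CT6 and CT10. Hsp90b1, the chaperone of that compartment, was 0.44 ± 0.07 log2 lower at CT6 and CT10 than at the other times, and Hspa5, its Hsp70, 0.36 ± 0.07 lower, from 520 ± 15.5 CPM at CT14 to 384 ± 20.2 at CT10 (SD, n = 2). Calr and Pdia4, which fold glycoproteins and form disulfide bonds, were 0.31 ± 0.04 and 0.25 ± 0.04 lower. Of the 19 genes, 9 passed this contrast and all 9 were lower, in a contrast that called 238 genes (146 higher, 92 lower). Over the 6 times 0 of the 19 passed over all genes by edgeR and 12 had an unadjusted p under 0.05, and the list score did not pass (adjusted permutation p = 0.0911). Monocyte and macrophage markers moved with them: 0 of 15 were above the other times at CT6 and CT10, with a median of -0.52 log2. Summed CPM of the folding genes stood at 3355 ± 84.4 and 3227 ± 80.8 at CT6 and CT10 and at 3811 to 3962 at the other times.

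Tsc22d3 rises with glucocorticoids in many cell types, and Il7r and Cxcr4 are known to respond to them in T cells, so a candidate explanation for CT10 is a shared glucocorticoid input. Cxcr4 followed Tsc22d3 with r = 0.71 and Il7r with r = 0.67, but the genes were picked for standing high at CT10. Without the CT10 libraries r was 0.46 (permutation p = 0.182, n = 10) and 0.12 (permutation p = 0.748, n = 10), so a shared glucocorticoid input cannot be told apart from something else shared at CT10. The circadian time itself stays open, and no hormone level was given.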
